A study of Mus musculus with 9 samples.

How the data were processed

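ATAC-seq was performed on endothelial cells sorted by fluorescence from mouse lung, with 3 libraries each of infant, young adult and mature adult mice, and 1 peak list per library was used. Per the file headers, each deposited list gives the chromosome, start and end of a peak and no height, score, p-value or read number. Per the submitters' processing notes the tools were cutadapt, Bowtie2 and Picard, without versions, and the genome build was mm10. The peak caller, its threshold and any shift of reads for the transposase's cut are not given in the sources used here. The same interval filled between 1 and 14 rows of a deposited list, and between 31.0% and 38.9% of the intervals were repeated. Each interval was therefore counted once, and the rows as deposited were used as an alternative. Peak widths ran from 150 bp upward. Whether the deposited starts count from 0 or from 1 is not stated, so positions are given as in the lists and may be off by 1 bp.

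Sequencing depth is unknown, and a library sequenced more deeply can yield more called peaks. No interval or detection limit based on reads was therefore given, and a region without a peak is not shown to be closed. The number of peaks, the covered length, the percent of peaks whose centre lay within 1 kb of a gene end and the Jaccard index of covered bases were computed per library or pair of libraries. Peaks of all libraries that overlapped by at least 1 bp were merged into 126907 regions, and a library was counted as having a region when at least 1 of its peaks overlapped it.

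Genes were taken from a table of 21887 protein-coding RefSeq genes of assembly GRCm38.p6, the same build as mm10, which gives each gene's start and end without strand, exons or introns. Distances to a transcription start site, planned at first, were replaced by distances to either end of the gene, and a region is described only as inside or outside a gene. A peak was assigned to the gene whose body held its centre, or otherwise to the gene with the nearest end within 100 kb. Lists matched by a peak score were planned and could not be made without a score. All peaks were used instead, scaled to the library's total, as laid down for that case. Regions to be named were ranked by the mean percentile of the peak's width within its library in place of a score. Motif searches for 32 sequence patterns were planned and are not reported, because no genome sequence was used here.

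The number of peaks per gene, scaled to the library's total, was tested as log2(number + 0.5) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend) over all 9 libraries in 1 fit, for the 14450 genes with a mean of at least 1 peak, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Changes are on the log2(number + 0.5) scale, which understates changes of genes with few peaks and, for genes at 0 in a group, depends on the added 0.5, so peak numbers are printed in place of fitted changes. Libraries of an age with equal peak numbers leave little spread, so a very small p can go with a small change. Aurka, with 1 peak in every library, had a limma adjusted p of 0.000135 for mature adult against infant after scaling. Per-library values were tested by exact permutation of the F statistic over all 280 splits into 3 groups of 3, two-sided, and similarity one-sided. Gene lists were tested as the percent of assigned peaks at their members, adjusted over the 26 lists; 423 of their 427 symbols were found in the gene table. Each list was also set beside 10000 random lists, in which every member was replaced by a gene of similar mean peak number. For lists of other cell types a 95% interval of the difference between lists was taken over 10000 resamplings of the members, a step added after the data had been seen. It replaced a first rule, overlap of the intervals of single lists, under which the explanations by a lower share of endothelial cells and by weak peaks at inactive genes had both stayed open. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

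The gene test was tested on simulated data for the comparison of mature adult with infant libraries, with 100 genes changed in each direction among 15150 tested. It recovered 14% of the genes raised 2-fold and 36% of those raised 4-fold, and 18% and 36% of those lowered 2-fold and 4-fold. Of 21 genes changed 4-fold with at least 10 peaks it recovered 76.2%. It also called 28 of 14950 unchanged genes, 35% of all calls in that simulation, so that more than the nominal share can be false. The median fitted change of genes lowered 4-fold was -1.78. The median shift in the simulation was -0.0015, against a median change of all genes of 0.14 in the data for this comparison. The simulation therefore did not cover calls that arise after scaling because the adult lists were shorter. The false share among the 5055, 6340 and 122 genes called between the ages was not measured.

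Groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For each pair of ages the 12 genes with the largest rise and the 12 with the largest fall past the threshold, whose libraries did not overlap, were named, together with up to 4 members of each list past the test, and peak numbers at Pecam1, Cdh5, Kdr and Erg. Not every gene picked by this rule is reported here; all stayed in the gene test and in its counts. Alternatives were unscaled numbers, a pseudocount of 1, no filter or a mean of at least 3 peaks, covered bases in place of peak numbers, peaks within 10 kb of a gene only, chromosomes 1 to 19, a 2.5 kb window, stricter or looser region overlap, the replicate number as a block and leaving out each library. An equal number of widest peaks per library (59793), the omission of 2 adult libraries, infant replicate 3 as the only infant library, unscaled list numbers, chromosomes 1 to 19 for genes and the rows as deposited were added after the data had been seen.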

Results

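The assay for transposase-accessible chromatin (ATAC-seq), in which a transposase cuts and tags DNA that is not packed in closed chromatin, was run on endothelial cells sorted from mouse lung at 3 ages. The libraries were 3 from infant mice, 3 from young adult mice and 3 from mature adult mice. The labels give no age in days and do not say whether the 3 libraries of an age came from separate animals, so p-values measure only the spread between these libraries. According to its title and design text, the study asks how chromatin changes as endothelial cells pass from an angiogenic state, in which vessels still grow, to a quiescent adult state. Each library is represented by its list of peaks, the stretches of DNA called open, without a height or read number per peak. The lists held between 59793 peaks (mature adult replicate 1) and 94646 peaks (infant replicate 1), and between 90.5% and 93.6% of a library's peaks were assigned to a protein-coding gene. Sequencing depth is unknown here, so the length of the list is the only measure of how much was called in a library. Genes used by endothelial cells carried many peaks at every age. Pecam1, an adhesion molecule of endothelial junctions, had 24, 23 and 23 peaks in the infant libraries, 25, 24 and 22 in the young adult libraries and 21, 23 and 24 in the mature adult libraries. Cdh5 (VE-cadherin) had between 22 and 31 peaks per library, Kdr (VEGF receptor 2) between 27 and 37, and Erg, an endothelial transcription factor, between 22 and 36.

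More peaks were called in infant than in adult libraries. The infant libraries held 91182 ± 3058 peaks (mean ± SD, n = 3), the young adult libraries 67922 ± 413 and the mature adult libraries 62369 ± 2298, a 1.46-fold difference between infant and mature adult. The difference between ages exceeded the spread between replicates (exact permutation test of the F statistic over 280 splits, two-sided, p = 0.00357, the smallest p these splits can give). The peaks covered 50.0 ± 3.10 Mb in infant, 35.4 ± 2.23 Mb in young adult and 32.4 ± 2.41 Mb in mature adult libraries (exact permutation p = 0.0107), while the mean peak width of 549, 522 and 518 bp did not differ detectably (exact permutation p = 0.271). Peaks within 1 kb of either end of a gene made up 15.9 ± 0.600% of the infant, 19.1 ± 0.271% of the young adult and 19.8 ± 0.481% of the mature adult peaks (exact permutation p = 0.00357). In number these peaks went the other way, from 14511 ± 120 in infant to 12969 ± 234 and 12343 ± 160 in the adult libraries. The share of gene-end peaks did not differ when an equal number of the widest peaks was taken from every library, with an infant to mature adult ratio of 1.01 (exact permutation p = 0.557).

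**Figure D1:**
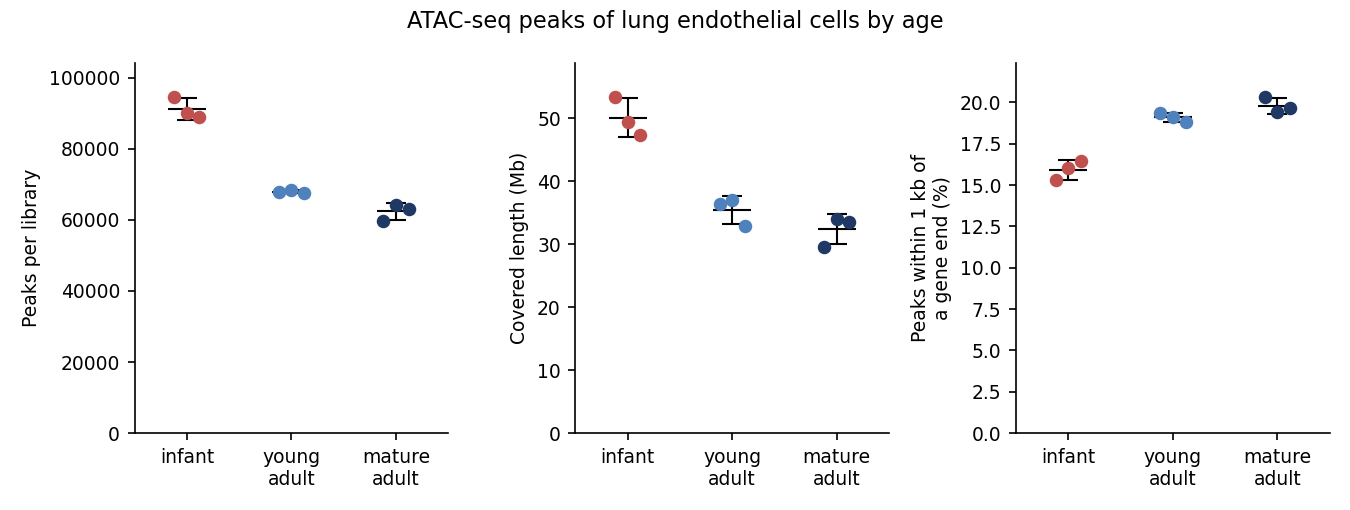
Number of peaks, covered length in megabases and percent of peaks within 1 kb of a gene end (vertical axes) in each library, by age (horizontal axis); points are libraries and bars the mean ± SD of 3 libraries. The infant libraries, with 88856 to 94646 peaks, lie above the adult libraries, which have 59793 to 68366.

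Merging the peaks of all libraries gave 126907 regions, of which 41144 were open in all 9 libraries. Regions open in all 3 infant libraries and in no adult library numbered 12315, and regions open in all 6 adult libraries and in no infant library 871. Among the infant regions with the widest peaks within their libraries, 1 lay inside Fbn2, which encodes the microfibril protein fibrillin 2, on chromosome 18 from 58209059 to 58211211 (mm10), 437 bp from a gene end. Others lay inside Bnc2, a zinc finger transcription factor gene (chromosome 4, 84674407 to 84676248, 702 bp from a gene end), inside Gpr37 (chromosome 6, 25688985 to 25690666, 155 bp from a gene end) and inside Rad51b (chromosome 12, 79511305 to 79512843). The remaining 2 lay outside genes, on chromosome 18 from 68742193 to 68743751 and on chromosome 19 from 28124994 to 28126463. Of the adult regions named by the same rule, 1 lay 42847 bp from the nearest end of Angpt1, which encodes a ligand of the endothelial receptor Tek that stabilises vessels (chromosome 15, 42719360 to 42720288). Another 3 lay inside Ankrd29 (chromosome 18, 12257654 to 12258846), Fer, a tyrosine kinase gene (chromosome 17, 64106379 to 64107237), and Speer2, a member of a multi-copy family whose peaks are uncertain (chromosome 16, 69861643 to 69862622). The other 2 lay 46868 bp from an end of Tmeff2 (chromosome 1, 51233679 to 51234597) and far from any gene on chromosome 14, from 109896209 to 109897327. Lrmda held 20 infant regions, Wwox 19, Auts2 and Rbms3 16 each, Ptprm 15 and Mecom 14. These genes held 25, 11, 8, 8, 26 and 14 regions open in all 9 libraries. Zbtb16, which encodes the transcription factor PLZF, held 7 adult regions, Coro2a 5, and Aff3, Prkce, Sema5a and Tacc1 4 each. Their regions open in all 9 libraries numbered 14, 2, 30, 57, 11 and 8. Mast4 held 12 infant and 3 adult regions. The counts were not set against gene length, so they do not mark genes as particular to an age. Regions of both classes lay mostly away from gene ends, with 7.16% of the infant and 3.90% of the adult regions within 1 kb of a gene end. The share was 12.2% for all merged regions and 25.1% for the regions open in all 9 libraries. With an equal number of widest peaks per library the infant class held 4862 regions and the adult class 2964.

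Libraries of the same age shared more of their covered bases than libraries of different ages. The Jaccard index of covered bases, shared length over joint length, averaged 0.748 between infant libraries, 0.710 between young adult libraries and 0.720 between mature adult libraries. It was 0.574 between infant and young adult libraries, 0.526 between infant and mature adult libraries and 0.696 between young and mature adult libraries. Within ages it averaged 0.726 and between ages 0.598, a difference of 0.128 (exact permutation test over 280 splits, one-sided, p = 0.00714). For the 2 adult ages alone the difference was 0.0191 (exact permutation p = 0.200, where 3 libraries against 3 cannot go below 0.100). The index cannot exceed the ratio of the 2 covered lengths, so its values between infant and adult libraries are limited by the longer infant lists. With an equal number of widest peaks the difference over all 3 ages was 0.118 (exact permutation p = 0.00714). Covered length still differed 1.34-fold there between infant and mature adult libraries. Young adult replicate 3 and mature adult replicate 1 stood apart from the other adult libraries, with 4901 and 4536 regions found in no other library against 1211 to 2003 in the other 4, and with mean peak widths of 487 and 495 bp against 530 to 541 bp.

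**Figure D2:**
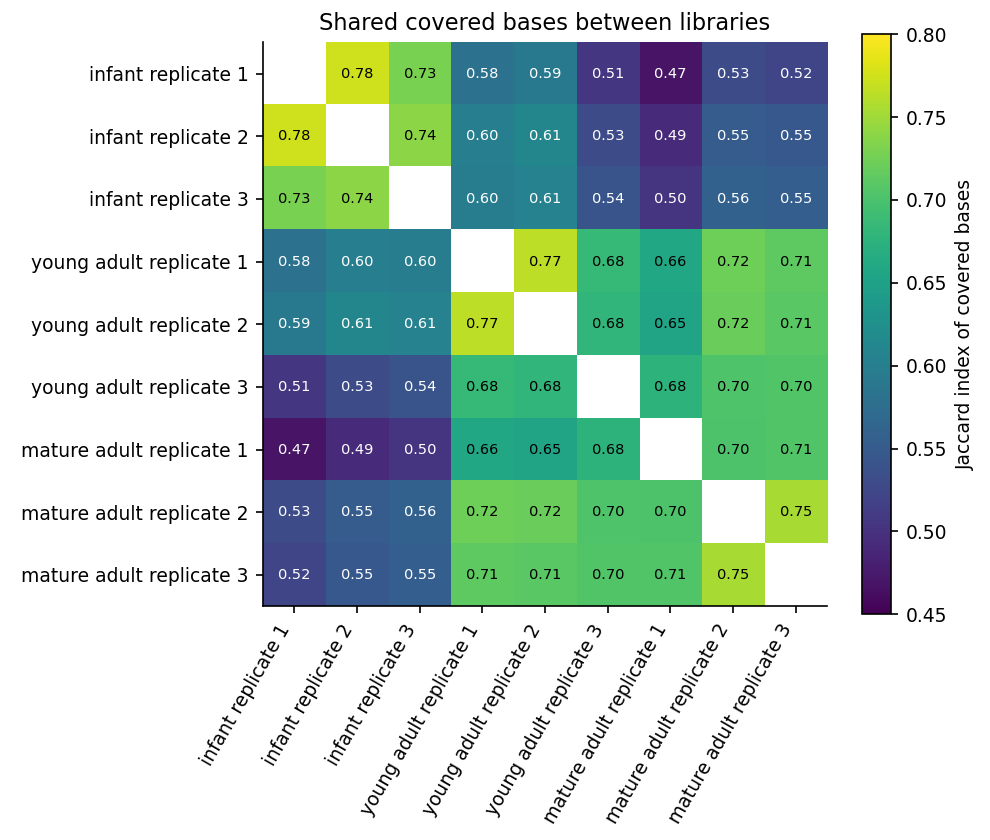
Jaccard index of covered bases for each pair of libraries, named on both axes by age and replicate; colour and printed value give the index and the diagonal is left blank. The 3 infant libraries share 0.729 to 0.775 with each other and at most 0.610 with an adult library.

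Between infancy and young adulthood, the genes with the largest falls lost most or all of their peaks. The ranking itself favours such genes, since from a given infant number the fall is largest where no peak is left. In the fixed lists 11 of 24 extracellular matrix genes fell and 3 rose as a share (13 and 4 adjusted over the list alone), and 6 of 11 fibroblast and mural genes fell and 1 rose as a share (7 and 1 adjusted over the list alone). Lamb1, which encodes the laminin beta 1 chain of basement membranes (chromosome 12, 31265146 to 31329644), had 14.3 ± 1.15 peaks in infant and 0.333 ± 0.577 in young adult libraries (n = 3 each, limma adjusted p = 0.00145). Col6a3, a collagen VI chain (chromosome 1, 90766860 to 90844001), had 7.67 ± 1.15 peaks in infant libraries and none in any of the 6 adult libraries (adjusted p = 1.35e-06). Sfrp1, a secreted antagonist of Wnt proteins (chromosome 8, 23411383 to 23449632), fell from 7, 7 and 5 peaks to none (adjusted p = 1.72e-06). Coro2a, a coronin of the actin cytoskeleton (chromosome 4, 46536937 to 46601929), rose from 2.67 ± 1.15 to 10.3 ± 0.577 peaks and held 5 of the regions found only in adult libraries (adjusted p = 0.000739).

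Several other genes lost all their peaks between these ages. Vsnl1, a neuronal calcium sensor gene, had 8, 7 and 6 peaks in infant and none in young adult libraries. The same held for Sema4f, a semaphorin gene (7, 6 and 6 to none), Vtcn1 (9, 5 and 5 to none) and Epsti1 (6, 5 and 6 to none). Gsg1l (7, 5 and 5 to none) and Ecrg4 (7, 6 and 4 to none) did likewise. Flrt1 fell from 11, 12 and 11 to 1, 0 and 0 and Pdzrn4 from 10, 9 and 7 to 0, 0 and 1. The adjusted p of these genes lay between 3.67e-09 for Sema4f and 0.00784 for Pdzrn4. Members of the fixed lists fell as well. Tgfb2, a TGF-beta ligand gene, fell from 20, 19 and 20 to 6, 5 and 6 peaks (adjusted p = 0.00163). Prox1, the transcription factor that specifies lymphatic endothelium, fell from 6, 5 and 7 to 1, 1 and 2 (adjusted p = 0.0153) and Mmrn1 from 8, 8 and 6 to 2, 3 and 3 (adjusted p = 0.0203). Plagl1, an imprinted transcription factor gene, fell from 6, 7 and 8 to 1, 2 and 2 (adjusted p = 0.00150), and Gja5, the arterial connexin 40 gene, from 11, 9 and 10 to 5, 6 and 5 (adjusted p = 0.00571). Rising genes had fewer peaks. Psmb9, an immunoproteasome subunit gene, had none in infant and 1, 1 and 2 in young adult libraries (adjusted p = 0.000739). Chmp4c rose from 1 in each to 4 in each (adjusted p = 0.000691) and Supt4a from 1 in each to 4 in each (adjusted p = 0.000739). Ms4a4a went from none to 2, 2 and 3 (adjusted p = 0.0103) and 2210408I21Rik from 1, 1 and 0 to 4, 4 and 7 (adjusted p = 0.00186). Rasgrp1 (1 in each to 5, 6 and 2), Tmem213 (1, 0 and 0 to 1, 3 and 2) and Gpr82 (1, 0 and 2 to 3, 4 and 4) rose after scaling, with adjusted p of 0.0624, 0.0766 and 0.108 on unscaled numbers. Gm1966, Btbd35f25 and Adam6b were also called, and their peaks are uncertain because these genes have near-identical copies.

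In all, 5055 of 14450 genes with a mean of at least 1 peak passed the test between infant and young adult libraries, 3703 higher and 1352 lower in young adults, on peak numbers scaled to the library's total. Without scaling, 164 were higher and 2527 lower. The 2 scales shared 164 higher and 1339 lower calls. Of the 3703 higher calls, 2291 were genes with the same number of peaks in all 6 libraries, whose share rose because the adult lists were shorter. Scaling moved the median change of all genes to 0.13 on the log2 scale, against -0.25 unscaled. An equal number of widest peaks per library gave 1393 genes. Without young adult replicate 3 and mature adult replicate 1 the count was 5694.

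Between infant and mature adult libraries, the genes with the largest falls had no peak left at the later age. Here too the ranking favours genes that reach 0. Tbx5 and Col1a2 belong to the list of fibroblast and mural genes, of which 5 of 11 fell and 1 rose. Tbx5, a T-box transcription factor gene (chromosome 5, 119796514 to 119885220), had 12.3 ± 1.15 peaks in infant, 1.33 ± 0.577 in young adult and none in mature adult libraries (n = 3 each, limma adjusted p = 1.28e-05 against infant), and 8 of the regions found only in infant libraries. Wnt5a, a non-canonical Wnt ligand gene (chromosome 14, 28504543 to 28527448), had 8, 7 and 6 peaks in infant and none in mature adult libraries (adjusted p = 0.00108). Col1a2, a chain of fibrillar collagen I, fell from 13.7 ± 0.577 to 2.33 ± 0.577 peaks (adjusted p = 0.000135), and Hmga2, a chromatin protein of fetal and proliferating cells, from 14.3 ± 1.53 to 1.67 ± 1.15 (adjusted p = 0.000954). Kdm6b, a histone H3 lysine 27 demethylase gene, rose from 4.33 ± 0.577 to 7.33 ± 0.577 peaks (adjusted p = 0.000224).

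Many genes had no peak in any mature adult library. Among them were Ephb2, an ephrin receptor gene (13, 11 and 7 peaks in infant libraries), Trim67 (9 in each), Plekhh2 (10, 6 and 10) and Mapk4 (8, 8 and 7). P4ha3, a collagen prolyl hydroxylase gene (7 in each), Gdf10, a TGF-beta family ligand gene (8, 6 and 7), Arsi (8, 9 and 6), Sv2c (8, 9 and 5) and Gm44812 (8, 5 and 11) were others, as were Col6a3 and Vsnl1. Their adjusted p lay between 3.77e-09 for P4ha3 and 0.00309 for Ephb2. The small p of P4ha3 goes with equal numbers in the libraries of each age, which leave little spread. Of the fetal growth and imprinted genes, 8 of 15 fell. Igf2bp2, an RNA-binding protein gene of fetal tissues, fell from 5, 7 and 7 peaks to none (adjusted p = 7.28e-06) and Igf1 from 16, 15 and 17 to 2 in each (adjusted p = 0.000559). Dkk2, a Wnt modulator gene, fell from 18, 18 and 17 to 4, 5 and 4 (adjusted p = 0.000135). Itga9, an integrin gene of lymphatic endothelium, fell from 43.0 ± 3.46 to 13.0 ± 1.00 (adjusted p = 0.000135), and Nid2, a basement membrane protein gene, from 13, 11 and 13 to 4 in each (adjusted p = 0.000136). Nrp2, a co-receptor for VEGF-C and semaphorins, fell from 21, 21 and 17 to 6, 6 and 7 (adjusted p = 0.000539), and Nr2f2, the transcription factor of venous identity, from 15, 14 and 13 to 3, 7 and 6 (adjusted p = 0.0288). Cxcr4 fell from 16, 16 and 15 to 7 in each (adjusted p = 0.00268) and Crebbp, a histone acetyltransferase gene, from 8, 10 and 6 to 2 in each (adjusted p = 0.000820). Hes1, a Notch target, fell from 31, 26 and 31 to 12, 15 and 14 (adjusted p = 0.00519), a direction that turned when only peaks within 10 kb of a gene were used. Genes that rose on both scales were Sirpa (6 in each to 8, 10 and 8), Fibin (4, 5 and 5 to 7, 8 and 7), Sox18 (4 in each to 5 in each) and Icam2 (5, 6 and 6 to 7 in each). Nr4a2 (5, 5 and 6 to 7 in each), Gbp7 (2 in each to 3 in each), Psmb9 (none to 2 in each), Limd2 (none to 1, 3 and 3) and Prr9 (none to 3, 2 and 4) also rose on both. Adgrl4, Lpl and Hpgd, genes of the capillary or fatty acid lists, rose after scaling (adjusted p = 0.000691, 0.00301 and 0.000913) but had unscaled adjusted p of 0.0502, 0.0679 and 0.0951. The rises at Cdh12 (none to 10, 4 and 4), Ctnna2 (none to 10, 3 and 3), Cntn4 (0, 0 and 1 to 10, 3 and 3) and Galnt13 (none to 4, 1 and 2) were led by mature adult replicate 1, a library with many regions of its own. Young adult replicate 3, which also stood apart, had 7, 5, 4 and 3 peaks at these genes. The other young adult libraries had at most 1. The rises at Btbd35f25, Prl2c2, Gm1966, Gm5885, Zfp981 and 2210010C04Rik are uncertain because these genes belong to multi-copy families.

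**Figure D3:**
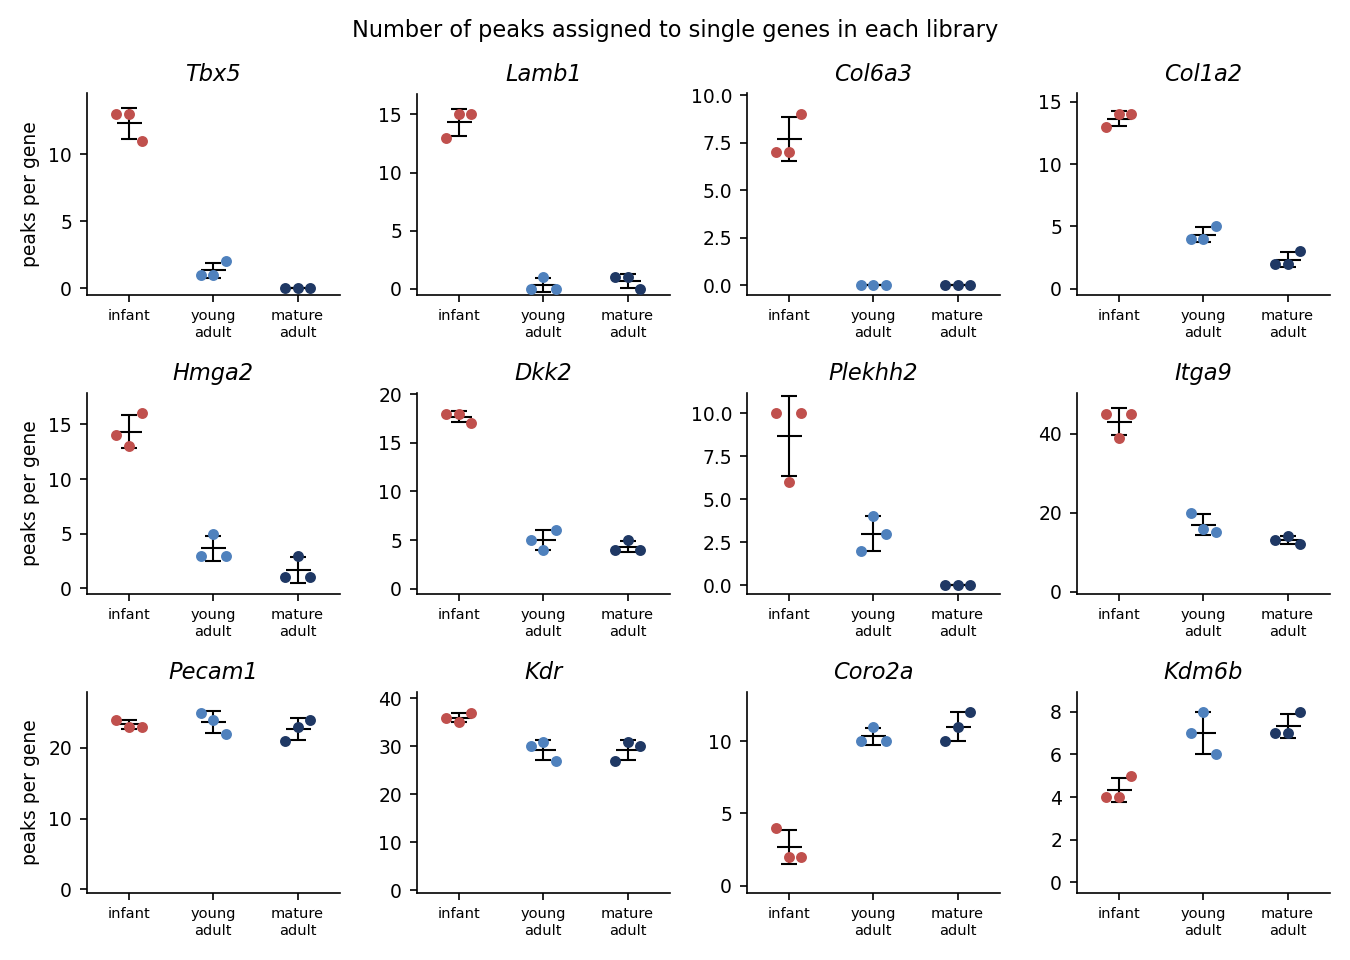
Number of peaks assigned to each of 12 genes (vertical axes) in the libraries of each age (horizontal axes); points are libraries and bars the mean ± SD of 3 libraries. Tbx5, Lamb1 and Col6a3 have at least 7 peaks in each infant library and at most 2 in an adult library, while Kdr falls in number and rises as a share of the library's peaks.

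Between infant and mature adult libraries 6340 genes passed the test, 4338 higher and 2002 lower in mature adults, and without scaling 209 were higher and 4245 lower. The 2 scales shared 209 higher and 2001 lower calls. This overlap is no independent support, because the adult lists were shorter. A gene that falls after scaling then also falls in number, and a gene that rises in number also rises after scaling. Of the scaled rises, 2330 were genes with an identical number of peaks in all 6 libraries. The median change of all genes was 0.14 scaled and -0.31 unscaled. An equal number of widest peaks gave 2268 genes, and without young adult replicate 3 and mature adult replicate 1 there were 6870.

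Between young and mature adult libraries far fewer genes were called, and their number depended on the libraries and settings used. Plekhh2 had 2, 4 and 3 peaks in young adult and none in mature adult libraries (limma adjusted p = 0.00175), after 10, 6 and 10 in infant libraries. Fasl, which encodes the death ligand of the Fas receptor, fell from 4 in each to 0, 1 and 0 (adjusted p = 0.0464), and Selplg, the gene of the selectin ligand PSGL-1, from 2, 3 and 1 to none (adjusted p = 0.0251). Tbx5 fell from 1, 1 and 2 to none (adjusted p = 0.00513) and Igf2bp2 from 1 in each to none (adjusted p = 0.000985). Trim30d, of a multi-copy family, rose from 1 in each to 3, 2 and 3 (adjusted p = 0.0134).

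Other genes without peaks in mature adult libraries were Il21r, a cytokine receptor gene (1, 4 and 2 in young adults), Gm40514 (2, 2 and 3), Sh3bgr (2 in each), Cd200r3 (2, 1 and 2) and Slamf9 (2, 1 and 2). So were Mpi, Napsa and Prnp (2, 2 and 1 for all 3 genes) and Trim52 (3, 1 and 2, a member of a multi-copy family). Their adjusted p lay between 1.80e-07 for Sh3bgr and 0.0433 for Il21r. The small p of Sh3bgr reflects equal numbers in the libraries of each age, at a change of only 2 peaks. On unscaled numbers the adjusted p of Fasl was 0.0551 and that of Il21r 0.0768. Rises were of 1 or 2 peaks in most libraries. Ceacam1, an adhesion molecule gene, went from 1 in each to 2, 3 and 2 (adjusted p = 0.00994) and LOC115488765 from 1 in each to 2, 2 and 3 (adjusted p = 0.0138). Myl6b, Pkd2l2, Efhb, Mybl1 and Dnajc25 went from 1 in each to 2 in each, and so did Zscan4d, a multi-copy gene. Pak3 (none to 1, 1 and 3) and Otog (none to 1 in each) rose after scaling, with unscaled adjusted p of 0.104 and 0.0833. Of regions open in all 3 young adult and no mature adult library there were 1110, 764 of them also open in all 3 infant libraries. Leaving out 1 adult library gave 1445 to 3282 of them, with 3282 without young adult replicate 3, 2073 without mature adult replicate 2, 1784 without young adult replicate 1 and 1741 without mature adult replicate 3. They included regions inside Auts2 (chromosome 5, 131537087 to 131539062) and inside Camk4, a calcium-dependent kinase gene (chromosome 18, 32938601 to 32939882). A region outside genes lay on chromosome 11 from 26209812 to 26211212. Regions open in all 3 mature adult and no young adult library numbered 256, a number reached by 5 of 10 splits of the adult libraries. It was between 430 and 891 without any 1 of the 6 adult libraries, and highest without mature adult replicate 1. Among them were regions inside Ppp1r10 (chromosome 17, 35929810 to 35931023), Trim30d (chromosome 7, 104501300 to 104502430) and Nln (chromosome 13, 104065732 to 104066250). The test called 122 genes, 21 higher and 101 lower in mature adults, and without scaling 15 higher and 119 lower, with 14 and 93 shared. With the replicate number as a block it called 66 genes, and among genes with a mean of at least 3 peaks 16, all lower. The median change of all genes was 0.09 scaled and 0 unscaled. The count rested on single libraries, being 424 without young adult replicate 3, 205 without mature adult replicate 2 and 186 without mature adult replicate 1. Without young adult replicate 3 and mature adult replicate 1 it was 572 (150 higher, 422 lower), with 98 of the 122 genes kept, and another split of the 6 adult libraries gave 127 genes.

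Of the 26 gene lists fixed beforehand, 19 differed between ages in their share of the assigned peaks. From infant to adult 7 of these fell in share, and so also in number of peaks, since the adult lists were shorter. Of the 19, 11 changed by more than the central 95% of 10000 random lists of genes with similar peak numbers. The other 8 lay within that range, namely the venous, epithelial, pan-endothelial, flow response, VEGF, chromatin enzyme, glycolysis and inflammation lists. The list of fibroblast and mural cell genes, which stand for cell types other than endothelium, fell most when all peaks were counted. With an equal number of widest peaks it changed by -0.44 on the log2 scale, less than the fetal growth (-0.62), lymphatic (-0.46) and epithelial (-0.45) lists, and with covered bases by -0.70, less than the fetal growth list (-0.74). It took 0.120 ± 0.00152% of the assigned peaks in infant, 0.0668 ± 0.00306% in young adult and 0.0686 ± 0.00468% in mature adult libraries (exact permutation test, Benjamini-Hochberg adjusted p = 0.0429, n = 3). Of its 11 tested members 5 fell and 1 rose between infant and mature adult (5 and 1 adjusted over the list alone). Besides Tbx5 and Col1a2, Cspg4, the gene of the pericyte proteoglycan NG2, fell from 9, 8 and 9 to 3 in each peaks, whereas Myh11, smooth muscle myosin, rose from 7 in each to 8 in each. The fetal growth and imprinted list fell from 0.174 ± 0.00754% to 0.119 ± 0.00551% and 0.0981 ± 0.0166% (adjusted p = 0.0232), with 8 of 15 members lower and 0 higher (8 and 0 adjusted over the list alone). The lymphatic list fell from 0.116 ± 0.00257% to 0.0785 ± 0.00179% and 0.0797 ± 0.00792% (adjusted p = 0.0440), with 2 of 9 members lower and 1 higher (3 and 1 adjusted over the list alone). The extracellular matrix list fell from 0.430 ± 0.00336% to 0.350 ± 0.0130% and 0.343 ± 0.00852% (adjusted p = 0.0429), with 11 of 24 members lower and 4 higher (11 and 4 adjusted over the list alone). In that list Fbn1, fibrillin 1, fell from 23, 22 and 19 to 8, 10 and 8 peaks (adjusted p = 0.00108) beside Nid2 and Col1a2, while Col4a2, a basement membrane collagen gene, had 30, 27 and 29 peaks in infant, 31, 29 and 28 in young adult and 23, 28 and 24 in mature adult libraries. The Wnt list fell from 0.303% to 0.251% (adjusted p = 0.0232), with 7 of 20 members lower and 5 higher, and the venous list from 0.171% to 0.147% (adjusted p = 0.0429), with 3 of 12 lower and 1 higher. The list of epithelial genes, another foreign cell type, fell from 0.0657% to 0.0464% (adjusted p = 0.0440), with 2 of 9 lower and 1 higher. These 3 lists had the same counts adjusted over the list alone. Of all 14450 genes tested 2002 were lower and 4338 higher as a share in mature adult than in infant libraries.

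The other 12 lists took a larger share of the peaks in adult libraries but had fewer or about as many peaks there, so that their direction turned on unscaled numbers. The share of the list of aerocyte genes, the large alveolar capillary cells that line the gas exchange surface, rose from 0.203 ± 0.00196% to 0.266 ± 0.00599% and 0.297 ± 0.0104% (exact permutation test, adjusted p = 0.0232), at 170 ± 4.62, 167 ± 4.16 and 171 ± 13.7 peaks. Of its 14 members 11 rose as a share between infant and mature adult (11 adjusted over the list alone). Sirpa and Fibin rose on both scales, whereas Ednrb had 18, 18 and 17 peaks in infant and 16, 18 and 18 in mature adult libraries and Apln 10, 10 and 11 and 11, 12 and 12. The antigen presentation list had 46.7 ± 2.31, 47.0 ± 1.00 and 46.0 ± 1.00 peaks in total while its share rose from 0.0559% to 0.0801% (adjusted p = 0.0232). In number 2 of its members rose and 3 fell between infant and mature adult. Of its 15 members 8 were higher and 1 lower as a share (11 and 2 adjusted over the list alone). The share of the general capillary list rose from 0.265% to 0.358% (adjusted p = 0.0440), with 8 of 14 members higher (8 adjusted over the list alone). That of the interferon list rose from 0.0938% to 0.123% (adjusted p = 0.0429), with 7 of 16 higher (7 adjusted over the list alone), and that of the fatty acid handling list from 0.152% to 0.195% (adjusted p = 0.0433), with 9 of 18 higher and 1 lower (9 and 2 adjusted over the list alone). These 3 lists showed no detectable difference in number (exact permutation p = 0.711, 0.275 and 0.221). Of all 14450 genes tested 4338 were higher as a share in mature adults, 2330 of them with an identical number of peaks in all 6 libraries. Members higher on both scales numbered 2 each in the aerocyte and antigen presentation lists and 1 in the interferon list. The general capillary and fatty acid handling lists had 0. The remaining 7 lists fell in number between infant and mature adult while their share was higher in adults, with adjusted p of the share between 0.0232 and 0.0440. The pan-endothelial list went from 348 ± 9.61 to 291 ± 19.1 peaks, the flow response and quiescence list from 282 ± 5.51 to 233 ± 17.1 and the VEGF and angiopoietin list from 244 ± 8.08 to 196 ± 17.1. The immediate early list went from 143 ± 1.53 to 126 ± 2.52, the chromatin enzyme list from 165 ± 4.93 to 130 ± 6.35, the glycolysis and hypoxia list from 145 ± 3.06 to 114 ± 7.02 and the inflammation list from 140 ± 7.57 to 100 ± 2.52. Klf2, a flow-induced transcription factor gene, had 8 in each peaks in infant and 8, 9 and 10 in mature adult libraries, and Jun 13, 13 and 14 against 14, 17 and 16. The lists of tip cell, cell cycle, TGF-beta and BMP, Notch, arterial, leukocyte and erythroid genes did not pass the test of the share (adjusted p = 0.804, 0.529, 0.317, 0.773, 0.538, 0.270 and 0.0882). On unscaled numbers 20 of the 26 lists passed, 0 higher and 20 lower in adults, among them these lists except the leukocyte list. The leukocyte genes had 21.7 ± 0.577, 22.7 ± 6.81 and 16.0 ± 1.00 peaks and the erythroid genes 22.0 ± 1.73, 15.0 ± 1.00 and 12.3 ± 1.53. The number of lists called was 8 when only peaks within 10 kb of a gene were used, where the extracellular matrix, Wnt, lymphatic, epithelial, general capillary, fatty acid handling, VEGF, flow response, inflammation, glycolysis and chromatin enzyme lists no longer passed. The fatty acid handling list also did not pass with covered bases (adjusted p = 0.0929) or an equal number of widest peaks (adjusted p = 0.0587), and the inflammation list did not pass with covered bases. With covered bases 20 lists passed, and 17 of the 19 were among them, so that some lists passed only there. The Wnt list changed by -0.21 on the log2 scale with all peaks and by -0.11 within 10 kb. With 1 library left out between 7 and 18 lists passed. With the replicate number as a block 0 lists passed, at the same changes. The smallest exact p is 0.0278 there before adjustment over the 26 lists, so lists could pass only if many reached it together.

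**Figure D4:**
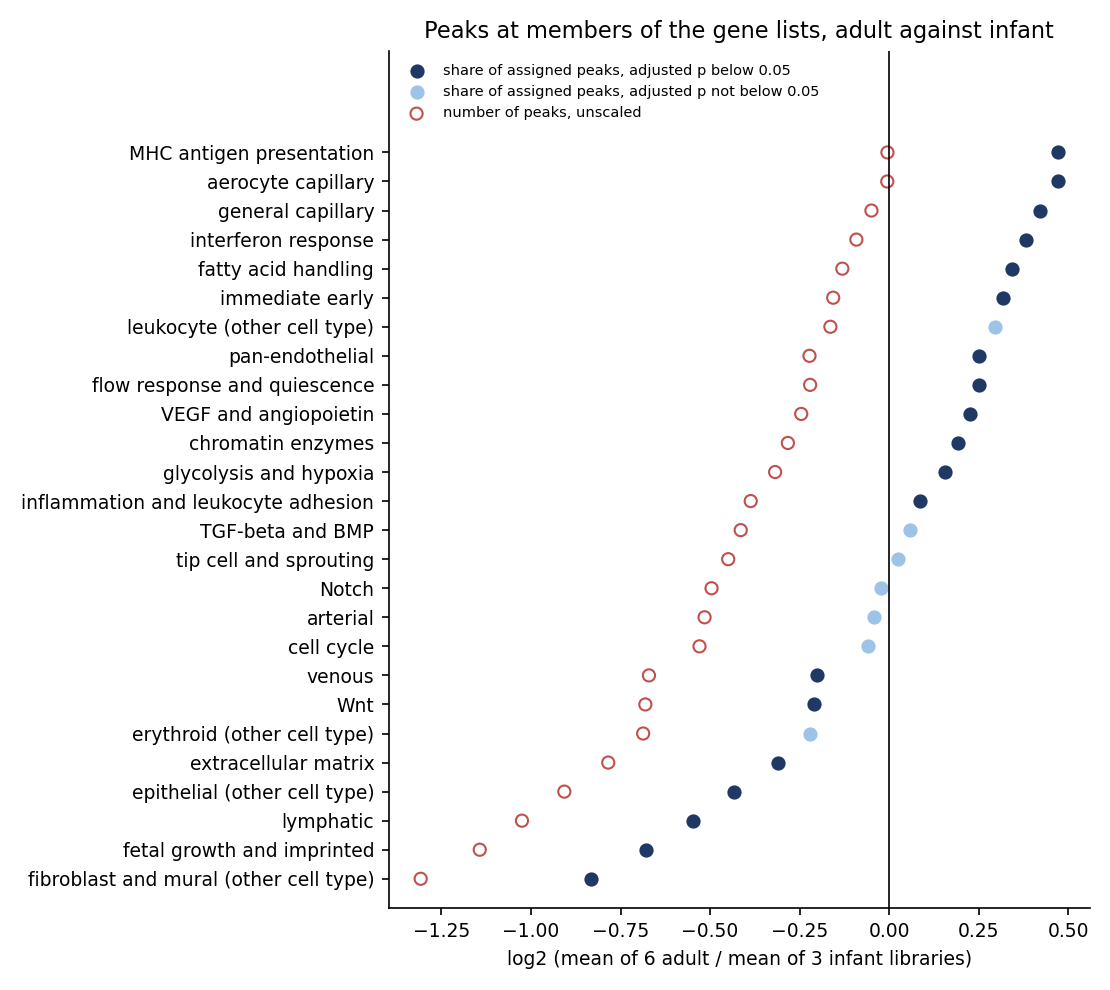
Change of the peaks at members of 26 gene lists as log2 of the adult mean (6 libraries) over the infant mean (3 libraries), on the horizontal axis, with the lists on the vertical axis; filled points give the share of assigned peaks and open points the unscaled number. The fibroblast and mural list is lowest on both measures (-0.83 as a share, -1.31 in number), and the 12 lists that rose in share lie below 0 in number.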

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

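The test of equal lists and the tests of added fibroblast, liver and neuron lists were written before their results were seen; the tests of gene-end peaks, of similarity of infant replicate 3, of epithelial, erythroid and leukocyte genes, of the spread between list members, of differences between lists and of other splits were chosen afterwards. Peaks on chromosome Y, which entered no comparison, stood out in 2 libraries. Infant replicate 1 had 7 and infant replicate 2 had 7 such peaks, at Uba1y, Kdm5d, Eif2s3y, Uty and Ddx3y. They were flagged for lying above 3, a bound for a count of 0 that holds for independent counts. Called peaks need not follow it. Infant replicate 3 and 5 adult libraries had 0, and young adult replicate 3 had 1, near Gm52481. The labels give no sex.

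Infant libraries held more peaks than adult libraries, and regions open in all 3 infant and no adult library outnumbered regions open in all 6 adult and no infant library, a class with a stricter rule. If male mice among the infants were the whole cause, infant replicate 3 would share no more with infant than with adult libraries. Its lowest Jaccard index with an infant library was 0.729, above its highest with an adult library, 0.606. A part played by sex beside age stays open. Infant replicate 3 shared 0.7295 and 0.7385 with the other infant libraries, which shared 0.7752 with each other. With mature adult replicate 1 it shared more than they did (0.5033 against 0.4684 and 0.493). With young adult replicate 2 its 0.6056 lay between their 0.5916 and 0.6101. A deeper or more sensitive peak call in infant libraries stays open. With the same number of widest peaks from each library the infant regions went from 12315 to 4862 and the adult regions from 871 to 2964; both lay above the other 83 splits (at most 339 and 350), which mix the ages, so that the comparison with those splits, planned as the test, decides nothing. Gene-end peaks were 1.18 times as many in infant as in mature adult libraries and all peaks 1.46 times, and depth cannot be told apart from age, which also stays open, because reads per library were not used here.

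The lists of fibroblast, mural and matrix genes took a larger share of the peaks in infant libraries. A lower share of endothelial cells in the infant sorts would raise all foreign markers alike only if the mix of other cells were the same, which was not tested. From infant to adult the fibroblast and mural list changed by -0.83 on the log2 scale and a second list of 20 fibroblast genes by -0.95. The epithelial list changed by -0.43, the erythroid list by -0.22 and the leukocyte list by 0.30. The leukocyte list lay above the fibroblast and mural list by 1.13 (95% interval over resampled members 0.48 to 1.97) and, with an equal number of widest peaks, by 0.57 (0.01 to 1.43). Only 5 of its 16 genes had a mean of at least 1 peak, and the interval leaves out the spread between libraries. Its share was 0.026% in infant, 0.0359 ± 0.0102% in young adult and 0.0278% in mature adult libraries. The epithelial and erythroid lists were not apart from either fibroblast list. A lower endothelial share thus stays open. More weak peaks at inactive genes in general would lower liver and neuron lists as much. These changed by 0.02 and -0.36, at percentiles 74.79 and 4.95 of the random lists. They lay above the second fibroblast list by 0.96 (0.22 to 1.61) and 0.59 (0.04 to 1.17). With an equal number of widest peaks the differences were 0.97 (0.31 to 1.60) and 0.67 (0.13 to 1.24). The intervals of the neuron list (-0.62 to -0.11) and of the second fibroblast list (-1.49 to -0.47) overlapped when taken singly. The values thus argue only against weak peaks as the whole of the second list's fall, and a part stays open. For the fibroblast and mural list the explanation stays open, since the neuron list lay above it by 0.47 (-0.12 to 1.22). With an equal number of widest peaks the liver list lay above it by 0.49 (-0.14 to 1.27). Fibroblasts or mural cells among the sorted infant cells may account for the pattern, since the second list lay below the bound of -0.45 under which 2.5% of 10000 random lists of similar peak number lay, although Col6a3 on it had been seen when the list was written and Wnt2 is also in the Wnt list. Mesenchymal genes that are open in infant endothelial cells themselves predict the same, and the sort leaves both open.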

How the results depend on the processing

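Equal numbers of widest peaks, the omission of 2 adult libraries, infant replicate 3 as the only infant library, rows as deposited, chromosomes 1 to 19 for genes and unscaled list numbers were chosen after the data had been seen. The cause of a change was not tested unless given. Whether the replicate numbers pair the libraries is not settled by the values. Deviations of same-numbered libraries correlated between -0.17 and 0.17 and those of differently numbered libraries between -0.23 and 0.28. For 5 of 9 libraries, all infant libraries among them, the best match at another age had their own number. With the replicate block the covered length ratio stayed 1.55 (exact permutation p = 0.0556), 66 genes were called between the adult ages, and 0 lists passed, with the same changes and a smallest possible p of 0.0278. The gene-end share ratio was 1.01 with equal numbers of widest peaks, against 0.804. The better-scored 50% of peaks, matched best-scored lists and all motif alternatives were not run, for lack of scores and of a genome sequence. Without reads per library, depth limits what the absence of a peak shows.

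Equal numbers of widest peaks gave 4862 infant, 2964 adult, 663 young adult and 467 mature adult regions, and 1393 genes (young adult against infant) and 2268 (mature adult against infant). Without young adult replicate 3 and mature adult replicate 1 there were 3873 young adult and 1548 mature adult regions and 572 genes between the adult ages. Leaving out each library gave 1445 to 3282 young adult regions, 430 to 891 mature adult regions and 99 to 424 genes between the adult ages (424 without young adult replicate 3, 205 without mature adult replicate 2, 186 without mature adult replicate 1). It gave 7 to 18 lists (7 without infant replicate 2, 8 and 10 without young adult replicates 1 and 2, 12 without infant replicate 3 and 12 without mature adult replicate 2). Unscaled numbers gave 2691 genes for young adult against infant. A mean of at least 3 peaks gave 1616, 2541 and 16 genes in the 3 comparisons, and peaks within 10 kb of a gene 8 lists.

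The shorter adult lists lower numbers against shares, but a rise in share need not turn into a fall in number. Between infant and mature adult 209 genes were higher on both scales. The aerocyte and antigen presentation lists showed no detectable difference in number (exact permutation p = 0.886 and 0.796). On unscaled numbers 12 lists turned direction, with log2 changes of -0.223 (pan-endothelial), -0.246 (VEGF), -0.221 (flow response), -0.0057 (aerocyte), -0.0498 (general capillary), -0.0052 (antigen presentation), -0.0919 (interferon), -0.387 (inflammation), -0.157 (immediate early), -0.131 (fatty acid), -0.319 (glycolysis) and -0.283 (chromatin enzymes). So did Aplnr (-0.124), Cav2 (-0.002), Cd93 (-0.0055), Cdh5 (-0.235), Cldn5 (-0.145), Dll4 (-0.0688), Ednrb (-0.0283), Flt4 (-0.124), Gpihbp1 (-0.0965), Id1 (-0.0535), Kdr (-0.293), Pecam1 (-0.0428) and Unc5b (-0.281) in mature adult against infant, and Nfkb1 (-0.0448) in young adult against infant. With peaks within 10 kb, Cldn5 (-0.332), H2-DMb1 (0.363) and Hes1 (0.196) turned. With covered bases Csf3 (-0.569) and Zscan4d (-0.0156) turned, and with equal numbers of widest peaks Gpihbp1 (-0.193) and Kdr (-0.0177). Of the calls of named genes, 62 were lost on unscaled numbers, 24 with covered bases, 64 with equal numbers of widest peaks, 39 with infant replicate 3 as the only infant library and between 3 and 17 when leaving out a library.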

Other observations

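Some proliferation genes lost peaks with age. The cell cycle list as a whole went from 91.7 peaks in infant to 59.7 in mature adult libraries (exact permutation p = 0.00357), while its share did not pass the test. These members were chosen after their values were seen. Mki67, the proliferation antigen, had 11, 10 and 12 peaks in infant, 6, 5 and 5 in young adult and 4, 5 and 3 in mature adult libraries (limma adjusted p = 0.00486 for mature adult against infant). Cenpf, a kinetochore protein gene, had 8, 7 and 7 in infant and 2, 3 and 2 in mature adult libraries (adjusted p = 0.00855), and Cdk1 7, 9 and 6 and 3, 3 and 2 (adjusted p = 0.0201). Ccna2, Aurka, Birc5 and Cenpa had 1 peak in every library. Of the 25 members 6 fell and 10 rose as a share, with 0 rising on both scales.

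Other splits of the libraries gave at most 319 regions for the class open in all 3 infant and no adult library (12315 in the real split) and at most 764 for the class open in all 6 adult and no infant library (871). In each class only 1 of 84 splits, the real one, reached the real number, a share under 0.05. The other splits mix the ages, so this says nothing about why the groups differ, list length included. The 764 is also the number of regions open in all infant and young adult libraries and in no mature adult library, itself a grouping by age. For the other comparisons 10 splits are too few for such a share. There 1 of 10 splits reached the 1110 regions of young adult libraries, with 870 as the highest other, and 5 of 10 reached the 256 of mature adult libraries, with 870 as the highest other. The 5055 and 6340 genes called in young and mature adults against infants were reached by 1 split each, with 0 genes in the highest other. The 122 genes between the adult ages were reached by 2 splits, with 127 in a split that placed young adult replicates 1 and 2 with mature adult replicate 2.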
